A study of Mus musculus with 10 samples.

How the data were processed

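The series measured RNA in P14 CD8 T cells taken from mouse tumours. P14 cells carry a transgenic T cell receptor that recognises the gp33 peptide, and B16-gp33 is a mouse melanoma line that expresses it. Per the labels, T cells of C57BL/6 background carried floxed Nfat5 alleles and either no Cre recombinase (called WT here) or Cre under the Cd4 promoter (called NFAT5 KO). They were activated in culture for 48 hours and transferred into mice bearing subcutaneous tumours, and CD8 T cells were sorted from the tumours 7 days later. RNA was extracted with a column kit and sequenced from Nextera XT libraries, per the labels' protocols. The 10 samples were 5 WT and 5 NFAT5 KO libraries. Their titles start with 678 (2 WT, 3 NFAT5 KO) or 679 (3 WT, 2 NFAT5 KO). The labels do not say what this prefix means, and it is called the label prefix here. No label says that each library came from a separate mouse, so p-values measure the spread between these libraries, part of which may be technical.

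The authors deposited 1 Salmon table per library, which lists an estimated count of reads, a TPM value, a length and an effective length for each of 140919 transcripts, per the file headers. The estimated counts need not be whole, and they were not normalized. TPM, an abundance scaled by effective length and by the library total, was used here only to weight transcript lengths in 1 alternative. Per the submitters' processing notes the tool was Salmon 0.14.1 and the builds GRCm38.p6 and mm10. The annotation release, strandedness setting and read trimming are not given in the sources used here. Salmon shares reads among similar transcripts by a model, so values of pseudogenes, paralogs and overlapping or antisense genes are less certain than those of other genes.

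Transcripts were matched to GENCODE M21 for GRCm38 by identifier without version. 140045 transcripts (99.38%) matched, and those that did not held 0.191% to 0.228% of the estimated counts of a library. Estimated counts were summed per gene and rounded to whole numbers, giving 54408 genes. Gene names, types and coordinates come from that annotation. No pair of libraries agreed within sampling noise, which argues against the same library being present more than once. Each was counted as 1 replicate, although this check cannot show that they came from separate mice.

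The comparison was NFAT5 KO minus WT over all 10 libraries, with no covariate. Genes were filtered with filterByExpr, which left 13081 genes, and scaled with TMM factors. They were tested with the edgeR 4.0.16 quasi-likelihood test with robust estimation (R 4.3.3), and p-values were adjusted with the Benjamini-Hochberg method at a threshold of 0.05. Changes are log2 fold changes with their standard error (SE), taken as the absolute fold change divided by the square root of the F statistic. Levels are CPM, counts scaled to a common library total, given as mean ± SD, and log2 CPM used a prior count of 2. The biological coefficient of variation was 35.7%. Library totals of 22444310 to 32001285 estimated counts set the counting error. Floors cover counting error only, while the SD and SE values also hold the spread between libraries.

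Gene lists for 18 T cell programs, for 10 other cell types and for 4 quality measures were fixed before the data were examined. They were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01. P-values were adjusted over the 18 program lists, and separately over the others. Each list is also given with the number of members past the threshold over all genes and adjusted over the list alone. For the lists of other cell types and quality, the mean log2 CPM per library was compared between genotypes with a two-sided exact permutation test over the 252 arrangements of the labels. The named genes were set by a rule, also fixed before. It took Nfat5, and the 10 higher and 10 lower genes with the smallest p-values among those past the threshold with a mean log2 CPM of at least 1. It also took Pdcd1, Havcr2, Lag3, Tox, Tcf7, Slamf6, Ifng, Tnf, Il2 and Gzmb whatever their p-value. From each program list it took up to 6 members past the threshold, or the 2 with the smallest p-values where none passed. Other genes named were chosen after their values were seen, and the text says so. A few genes that these rules took are not reported here, and the counts over lists and named genes include them.

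The alternatives were DESeq2 1.42.0 size factors, library size alone, no low-count filter, a filter of at least 5 CPM in at least 5 libraries and an offset for mean transcript length. Others were the label prefix as a block, each label prefix alone, the mean of melanoma or macrophage markers as a covariate, the DESeq2 Wald test, limma-voom with quality weights, and leaving out each library in turn. For the lists, an estimated correlation and fry were also run. The fit was tested on simulated data for the comparison of NFAT5 KO with WT, drawn for 12672 genes. It recovered 48 of 97 genes changed by 1 on the log2 scale (49.5%) and 71 of 95 genes changed by 2 (74.7%), and 3 of 122 calls were false. Of 200 simulated unchanged lists, 1 had a camera p-value below 0.05. The simulation drew each gene independently, so it does not test camera for lists whose members move together. The estimated correlation was 0.646 in the cell cycle list and 0.8 in the glycolysis list.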

Results

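RNA was measured in P14 CD8 T cells sorted from B16-gp33 melanomas 7 days after transfer, in 5 libraries of WT cells and 5 libraries of cells in which Cre under the Cd4 promoter acts on floxed Nfat5 (NFAT5 KO). NFAT5 is a transcription factor known for its role in the response to osmotic stress. The libraries held 22444310 to 32001285 estimated counts each. The design asks which genes tumour-infiltrating CD8 T cells express at another level when they lack NFAT5. The series title names T cell exhaustion, so genes tied to exhaustion, memory and effector function are given first.

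Nfat5 itself (ENSMUSG00000003847, GRCm38 chromosome 8, 107293470 to 107379517) was counted at 15.4 ± 3.81 CPM in WT and 15 ± 6.58 CPM in NFAT5 KO libraries (SD, n = 5 each). In WT libraries 678_2, 678_4, 679_3, 679_4 and 679_5 it stood at 18.02, 17.2, 18.3, 9.20 and 14.2 CPM. In NFAT5 KO libraries 678_3, 678_5, 678_6, 679_2 and 679_6 it stood at 12.2, 12.6, 11.6, 26.8 and 11.9 CPM. The log2 fold change was -0.04 (SE 0.27, adjusted p = 0.957), and without NFAT5 KO 679_2 it was -0.37 (adjusted p = 0.382). A count per gene does not separate reads of the floxed part from those of the rest, so this value does not test the genotype labels.

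NFAT5 KO cells had lower expression of genes of cell division and of a few exhaustion genes. Some of the tested immediate early genes, costimulatory genes and genes of tissue residency or trafficking were higher. The calls of these last 3 lists were lost with an estimated correlation (adjusted p = 0.0861, 0.289 and 0.208). Of 13081 genes tested, 1179 changed with genotype, 442 of them higher and 737 lower in NFAT5 KO cells (edgeR quasi-likelihood test, adjusted p below 0.05). Changes of at least 2-fold were found in 83 higher and 402 lower genes. Tox, a transcription factor needed for the exhausted state, fell from 76.7 ± 26.5 to 21.8 ± 4.22 CPM, and Pdcd1, which encodes an inhibitory receptor, from 331 ± 40.7 to 176 ± 62.0 CPM. At an unadjusted p below 0.05, 3041 genes differed. The count fell to 696 without WT 678_2, to 654 with the melanoma marker mean as a covariate and to 2 with the macrophage marker mean, which itself differed between the genotypes (r = -0.78 with genotype). The DESeq2 Wald test called 1893 genes.

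**Figure D1:**
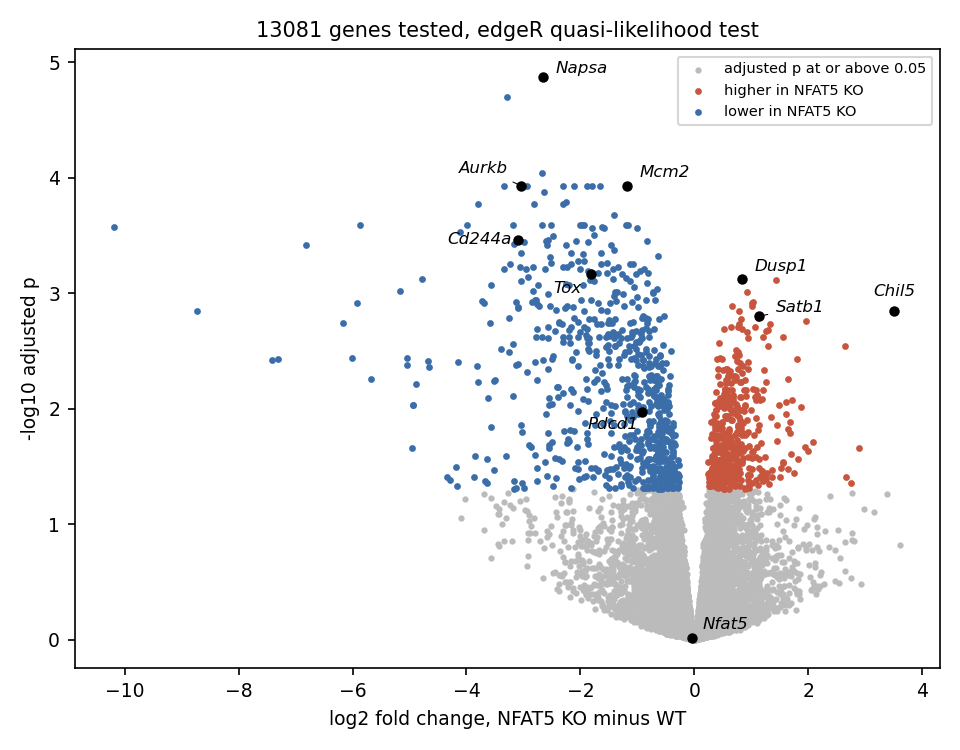
Each point is 1 of the 13081 genes, with the log2 fold change of NFAT5 KO minus WT on the x axis and the negative log10 of the adjusted p on the y axis. The 737 genes lower in NFAT5 KO reach further from 0 than the 442 higher ones, and Nfat5 lies at -0.04.

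The first component of the log2 CPM values held 31.6% of the variance and put the 5 WT libraries (-56.0 to -19.0) apart from the 5 NFAT5 KO libraries (10.7 to 80.4). Each label prefix held both genotypes. Libraries of prefix 679 alone (3 WT, 2 NFAT5 KO) called 325 genes. Of these, 324 (99.7%) had the same direction in the libraries of prefix 678 (2 WT, 3 NFAT5 KO), 256 of them at an unadjusted p below 0.05. Over all 13195 genes in both fits, called or not, 68.2% had the same direction. Prefix 678 alone called 0 genes with the edgeR test, with 1449 genes at an unadjusted p below 0.05. No gene passed the threshold for an interaction of genotype with prefix, and 377 had an unadjusted p below 0.05.

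**Figure D2:**
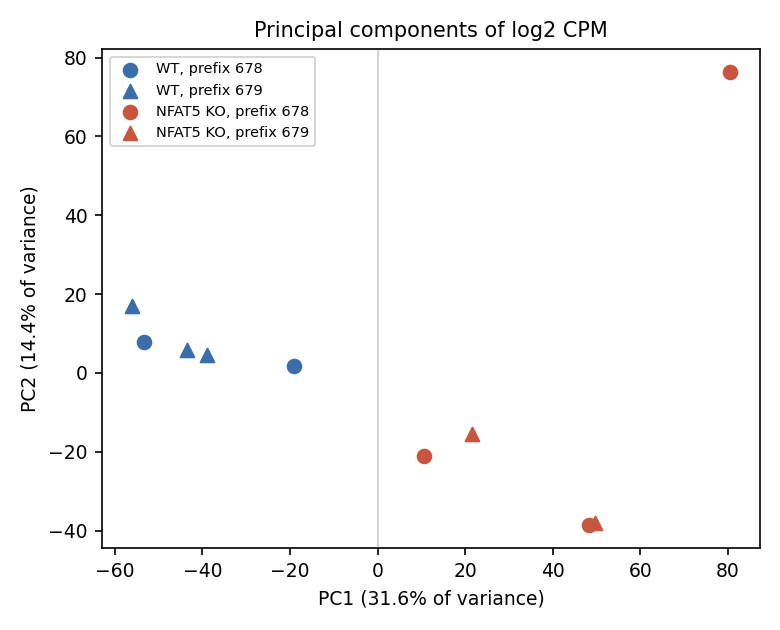
Scores of the 10 libraries on the first (31.6% of variance) and second (14.4%) principal component of log2 CPM, coloured by genotype and shaped by label prefix. WT libraries lie below 0 and NFAT5 KO libraries above 0 on the first component.

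Genes of DNA replication and mitosis showed the most uniform difference. All 29 tested members of the cell cycle list fell in NFAT5 KO cells, with a median log2 fold change of -2.59 (camera adjusted p = 8.41e-74, and adjusted p = 0.0250 with an estimated correlation). Mki67, the standard marker of proliferating cells, fell from 84.3 ± 28.7 to 9.30 ± 4.62 CPM, a log2 fold change of -3.18 (SE 0.34, adjusted p = 0.000258). The mitotic kinase Aurkb fell by 3.04 on the log2 scale (SE 0.28), and the cyclin Ccnb2 and the kinase Cdk1 had log2 fold changes of -3.80 (SE 0.37) and -2.63 (SE 0.25). The replication genes Mcm2, which encodes a helicase subunit, and Rrm2, which encodes a subunit of ribonucleotide reductase, fell by 1.18 (SE 0.10) and by 2.31 (SE 0.23). Other genes with the smallest p-values among the lower ones act in the same processes. They were Ncapg (-2.68), Cep55 (-3.34), Nusap1 (-2.93), Tacc3 (-2.12) and Fignl1 (-1.80), which act in chromosome segregation, cytokinesis or DNA repair, and the histone chaperone Asf1b (-2.31). The mean log2 CPM of the list lay between 6.69 and 7.41 in WT and between 4.01 and 5.31 in NFAT5 KO libraries. Markers of macrophages were also lower in NFAT5 KO libraries, at a mean log2 CPM of 0.900 ± 1.01 against 2.69 ± 0.514 in WT. With the macrophage mean as a covariate the list's median was -2.03, and 28 of its 29 genes kept an unadjusted p below 0.05.

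**Figure D3:**
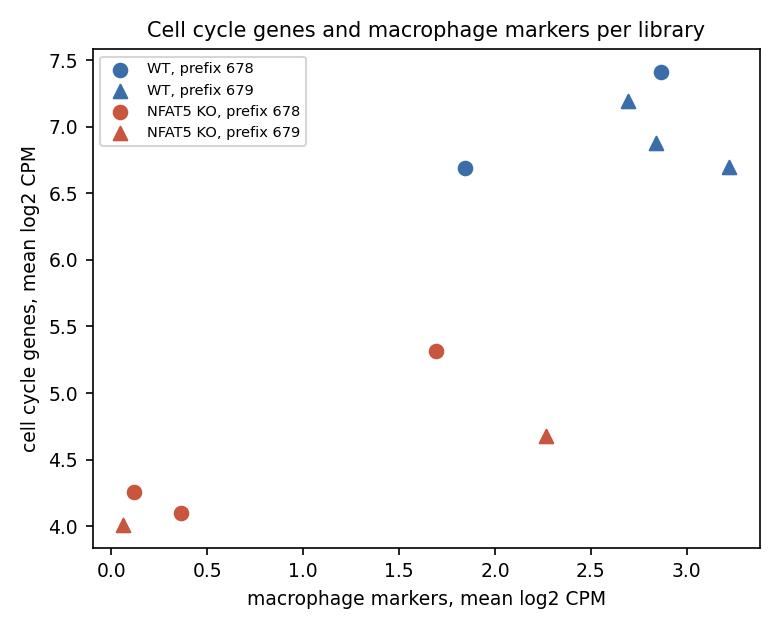
Each point is 1 library, with the mean log2 CPM of the macrophage markers on the x axis and that of the cell cycle genes on the y axis. The 5 WT libraries lie at 6.69 or above for the cell cycle genes and the 5 NFAT5 KO libraries at 5.31 or below.

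Among genes of inhibitory receptors, 3 of 15 tested members fell, 1 rose and 11 did not pass the test (adjusted over the list alone, 5 fell and 1 rose). Pdcd1 (chromosome 1, 94038305 to 94052553) had a log2 fold change of -0.91 (SE 0.19, adjusted p = 0.0107), and 1 NFAT5 KO library reached into the WT range. Cd244a, a receptor of the SLAM family, fell from 17.5 ± 8.48 to 2.04 ± 0.620 CPM (log2 fold change -3.10, SE 0.35), and Cd200 had a log2 fold change of -0.81 (SE 0.20). Vsir, which encodes the checkpoint protein VISTA, rose by 0.64 (SE 0.15). The calls of Cd200 and Vsir passed in 6 and 7 of the 10 fits that each left out 1 library, with highest adjusted p-values of 0.0661 and 0.0633. Havcr2 and Lag3, also inhibitory receptor genes, did not pass (log2 fold changes -0.29 and -0.07, adjusted p = 0.467 and 0.797), with ranges of -0.427 to -0.135 and -0.166 to -0.005 with 1 library left out. The list had a median of -0.29 and was called lower (adjusted p = 0.0305, and adjusted p = 0.289 with an estimated correlation). Its adjusted p was 0.0840 without WT 678_4, 0.0624 without NFAT5 KO 678_6 and 0.0516 without NFAT5 KO 679_2.

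Tox (chromosome 4, 6686353 to 6991557) fell by 1.82 on the log2 scale (SE 0.24, adjusted p = 0.000682), with each NFAT5 KO library below each WT library. It was the only lower member of the 14 tested exhaustion transcription factors past the threshold over all genes. Nr4a1, an early response gene of receptor signalling, rose by 0.82 (SE 0.19, adjusted p = 0.0201), and without NFAT5 KO 679_2, WT 678_2 or WT 679_3 its adjusted p was 0.0595, 0.0599 or 0.0531. The other 12 did not pass, and adjusted over the list alone 6 rose and 2 fell. The list was not called (median 0.29, adjusted p = 0.144), with a median of 0.188 to 0.396 with 1 library left out.

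Of 18 genes of stem-like and memory T cells, 5 rose and 2 fell. Satb1, a chromatin organiser of T cells, rose from 465 ± 124 to 1028 ± 197 CPM (log2 fold change 1.14, SE 0.17). Il7r, which encodes a receptor for a survival cytokine, rose by 1.21 (SE 0.24), and S1pr1, a receptor used to leave tissues, by 1.69 (SE 0.37). Ltb, which encodes lymphotoxin beta, rose by 0.46 (SE 0.08), and Bcl6 by 0.98 (SE 0.28, passing in 4 of the 10 fits that left out 1 library, with a highest adjusted p of 0.109). Dapl1 fell by 1.72 (SE 0.29). Tcf7 and Slamf6, the usual markers of stem-like cells, did not pass (log2 fold changes 0.18 and -0.66, adjusted p = 0.572 and 0.0972). Tcf7 was at 0.054 without WT 678_2. Slamf6 was called lower without WT 678_4 (-0.799, adjusted p = 0.0457) and with the DESeq2 Wald test (-0.665, adjusted p = 0.0303). The list had a median of 0.28 (adjusted p = 0.0143, and adjusted p = 0.334 with an estimated correlation), with 8 higher and 3 lower members adjusted over the list alone. Without WT 678_2 its adjusted p was 0.0553.

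**Figure D4:**
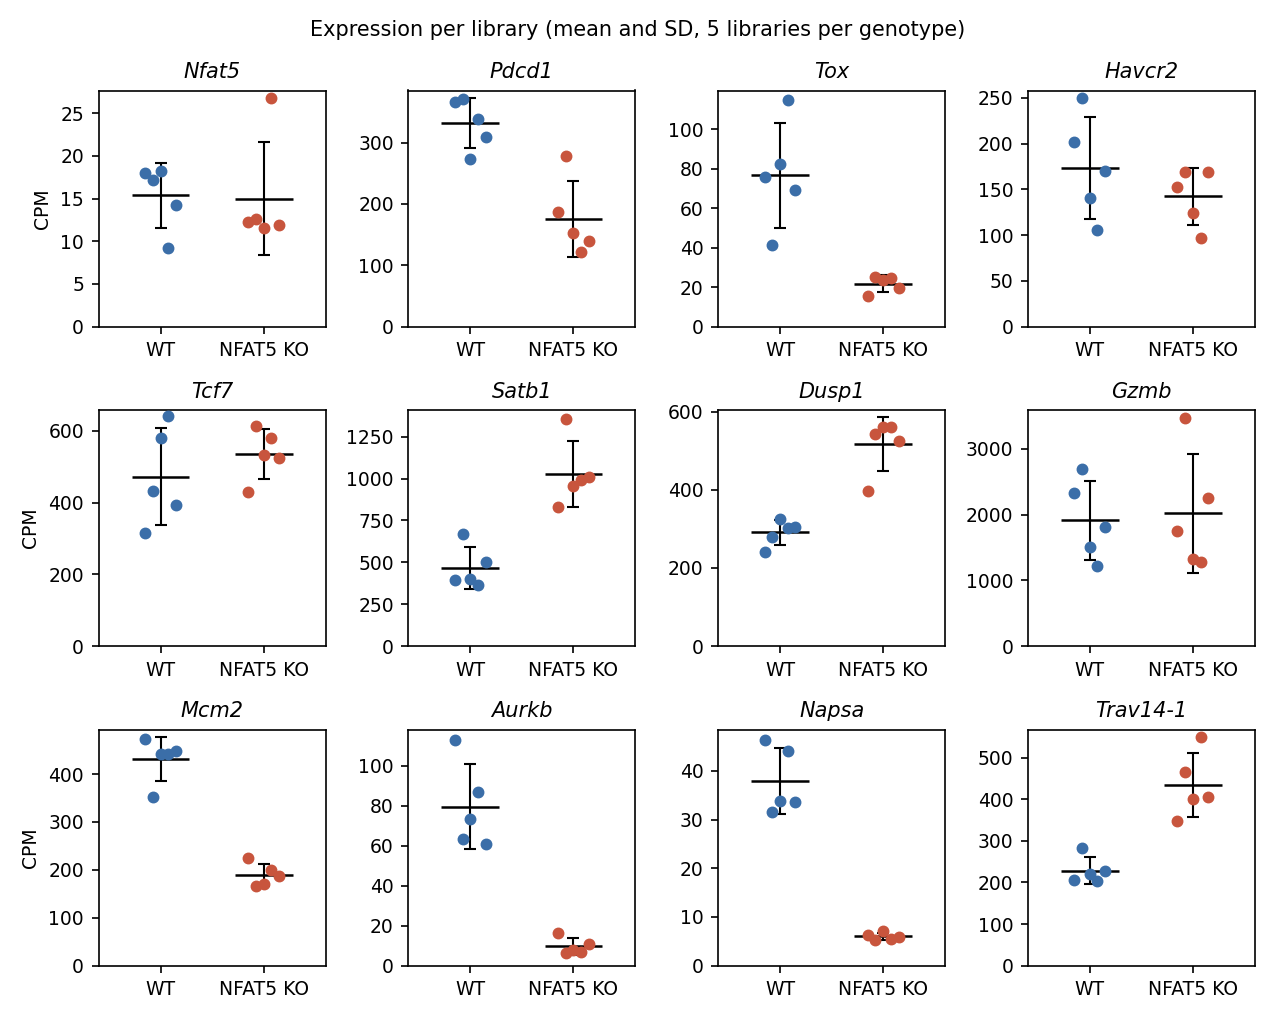
CPM of 12 genes in each library by genotype, with points for libraries, a bar for the mean and whiskers for the SD (5 libraries per genotype). Tox, Mcm2, Aurkb and Napsa are lower and Satb1, Dusp1 and Trav14-1 higher in each NFAT5 KO library than in any WT library, while Nfat5, Pdcd1, Havcr2, Tcf7 and Gzmb overlap.

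Effector cytokines and cytotoxic genes showed few differences. Ifng, Tnf, Il2 and Gzmb had log2 fold changes of 0.03 (SE 0.09), 0.24 (SE 0.13), -1.06 (SE 0.66) and 0.08 (SE 0.28), with adjusted p-values of 0.891, 0.315, 0.369 and 0.908. Il2 lay at 1.62 ± 0.638 CPM in WT and 0.776 ± 0.565 CPM in NFAT5 KO libraries, too low to settle a small difference. Of 21 cytotoxic genes 3 rose. These were Tbx21, which encodes the transcription factor T-bet (0.56, SE 0.11), Fasl, a death ligand (0.52, SE 0.12), and the granzyme gene Gzma (1.52, SE 0.40). Of 15 cytokine and chemokine genes 2 rose. These were Ccl5, a chemokine gene, from 585 ± 254 to 1436 ± 101 CPM, and Tnfsf14 (1.16, SE 0.32). Fasl, Gzma and Tnfsf14 passed in 5, 3 and 3 of the 10 fits that left out 1 library, with highest adjusted p-values of 0.0563, 0.0793 and 0.102. Neither list was called (medians 0.21 and 0.15, adjusted p = 0.142 and 0.378), and adjusted over the list alone the same numbers passed. Without NFAT5 KO 678_5 the medians were -0.011 and 0.045 and Gzmb was at -0.227, the cytokine median was 0.014 without WT 678_4, and the cytotoxic list passed without NFAT5 KO 679_2 (0.192, adjusted p = 0.0494). With 1 library left out Ifng ran from -0.047 to 0.059.

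Some immediate early and costimulatory genes were higher in NFAT5 KO cells. Of 16 immediate early genes 10 rose and none fell (median 0.66, adjusted p = 9.08e-10, and adjusted p = 0.0861 with an estimated correlation), and 13 rose adjusted over the list alone. Dusp1, a phosphatase that limits MAP kinase signalling, rose from 291 ± 32.5 to 518 ± 69.1 CPM (log2 fold change 0.83, SE 0.11, adjusted p = 0.000757). Zfp36, an mRNA-binding protein, rose by 0.80 (SE 0.14), Dusp2 by 0.39 (SE 0.08) and the transcription factor Egr1 by 0.68 (SE 0.14). Egr2 and Fosb rose by 0.90 and 1.03, each passing in 6 of the 10 fits that left out 1 library, with highest adjusted p-values of 0.0582 and 0.0653. Of 12 costimulatory receptor and ligand genes 6 rose (median 0.46, adjusted p = 1.47e-05, and adjusted p = 0.289 with an estimated correlation). Adjusted over the list alone, 8 rose and 1 fell. Cd40lg, the ligand of CD40, rose from 4.80 ± 2.26 to 18.7 ± 3.71 CPM, and Cd28 from 299 ± 26.8 to 400 ± 18.5 CPM. Slamf1 and Slamf7 rose by 0.65 (SE 0.12) and 0.67 (SE 0.14). Tnfrsf9 and Tnfrsf18, which encode receptors of the TNF family, rose by 0.68 and 0.62, but passed in 4 and 1 of the 10 fits that left out 1 library, with highest adjusted p-values of 0.0772 and 0.0940.

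Of 17 genes of tissue residency and trafficking 7 rose and none fell (median 0.37, adjusted p = 3.82e-05, and adjusted p = 0.208 with an estimated correlation). The number was 7 adjusted over the list alone. Cd69, an early activation and residency marker, rose from 167 ± 42.6 to 418 ± 115 CPM, a log2 fold change of 1.32 (SE 0.21). The chemokine receptor genes Cxcr4 and Cxcr3 rose by 1.08 (SE 0.23) and 0.37 (SE 0.08), and Rgs1, which dampens chemokine receptor signals, by 0.80 (SE 0.17). Cxcr6 and Itgb7 rose by 0.80 and 0.33. Cxcr3, Cxcr6 and Itgb7 passed in 7, 3 and 3 of the 10 fits that left out 1 library, with highest adjusted p-values of 0.0663, 0.0704 and 0.0685.

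Of 19 members of the cholesterol list 6 fell, none rose and 13 did not pass (9 fell adjusted over the list alone), with a median of -0.50 (adjusted p = 2.32e-06, and adjusted p = 0.289 with an estimated correlation). Idi1, Cyp51 and Stard4 had log2 fold changes of -1.61 (SE 0.30), -1.203 (SE 0.23) and -1.12 (SE 0.24). Fdft1 fell by 0.61, with an adjusted p of 0.0553 without WT 678_2 and of 0.109 with the length offset (-0.498).

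Other metabolic lists moved little. None of 15 glycolysis genes passed in the edgeR test (median -0.06, adjusted p = 0.740). The median ran from -0.172 to 0.016 with 1 library left out, and the list was called lower without NFAT5 KO 678_5 (-0.172, adjusted p = 0.0106). Hk2 and Slc2a1 had log2 fold changes of 0.24 and 0.25 (adjusted p = 0.463 and 0.481). The value of Slc2a1 rests on NFAT5 KO 678_5 at 289 CPM (the other NFAT5 KO libraries 127.5 to 163.2) and was -0.033 at its lowest with 1 library left out. The 27 genes of oxidative phosphorylation had a median of -0.14 and the list was called lower (adjusted p = 0.0152, and adjusted p = 0.566 with an estimated correlation), with Cox5b (-0.49) the only member past the threshold over all genes and 0 adjusted over the list alone. Without NFAT5 KO 678_5 the median was -0.09 (adjusted p = 0.0940), and Cox5b passed in 6 of the 10 fits that left out 1 library, with a highest adjusted p of 0.0814. Of 16 hypoxia genes Pfkfb3 rose by 0.85, passing in 5 of the 10 such fits with a highest adjusted p of 0.0672, and Pdk1 fell by 0.42 (SE 0.09). The hypoxia list was not called (median 0.11, adjusted p = 0.455), with the same 2 calls adjusted over the list alone, and its median turned to -0.086 without NFAT5 KO 678_5 (adjusted p = 0.477).

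Of 12 tested genes of the NFAT5 osmotic response 1 passed the test, and none fell at the threshold. Sgk1, a kinase gene induced by salt stress, rose from 34.2 ± 8.19 to 61.6 ± 4.89 CPM (log2 fold change 0.85, SE 0.16). The list was not called (median 0.10, adjusted p = 0.455, 1 member adjusted over the list alone), and its median turned to -0.078 without NFAT5 KO 678_5 (adjusted p = 0.99).

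Of 24 type I interferon response genes 4 fell and none rose, and the list was not called (median -0.17, adjusted p = 0.0770, 5 lower members adjusted over the list alone). Ifi27l2a fell from 276 ± 84.8 to 109 ± 7.79 CPM, and the antiviral genes Cmpk2 and Rsad2 by 1.56 (SE 0.32) and 1.72 (SE 0.37). Xaf1 fell by 0.71, passing in 8 of the 10 fits that left out 1 library, with a highest adjusted p of 0.0570. Leaving out NFAT5 KO 678_6, WT 679_3, WT 679_5 or NFAT5 KO 679_6 brought the list past the threshold (adjusted p = 0.0362, 0.0241, 0.0155 and 0.0480), and without NFAT5 KO 678_3 the median was -0.109 (adjusted p = 0.355).

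Stress and survival lists held changes in both directions and were not called. Of 19 genes of the integrated and ER stress response 2 rose and 3 fell (median 0.13, adjusted p = 0.451, with 6 and 3 adjusted over the list alone). The chaperone Dnajb9 rose by 0.76 (SE 0.13), and the amino acid synthesis gene Asns fell by 0.50 (SE 0.12). Ddit3 (0.77), Phgdh (-0.41) and Psat1 (-0.72) passed in 3, 9 and 4 of the 10 fits that left out 1 library, with highest adjusted p-values of 0.0911, 0.0627 and 0.0905, each without WT 678_2. Of 12 heat shock genes Hspa8 and Hsp90ab1 rose by 0.37 (SE 0.08) and 0.30 (SE 0.07), and Hspb1 fell by 1.88 (SE 0.44). Hsp90ab1 and Hspb1 lost their calls without WT 678_2 (adjusted p = 0.0569 and 0.0545). The heat shock list had a median of 0.29 (adjusted p = 0.0511, with 5 higher and 1 lower adjusted over the list alone). It passed without NFAT5 KO 679_2 (0.0133), WT 678_4 (0.0382) or WT 679_4 (0.0280), and without NFAT5 KO 678_5 its median fell to 0.139 (0.204). Of 14 apoptosis regulators 3 rose and 1 fell. The pro-apoptotic gene Bax rose by 0.55 (SE 0.11). Pmaip1 and Fas rose by 0.57 and 0.61, passing in 7 and 2 of the 10 fits, with highest adjusted p-values of 0.0570 and 0.0988 (list median 0.17, adjusted p = 0.142, with 4 higher and 1 lower adjusted over the list alone).

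**Figure D5:**
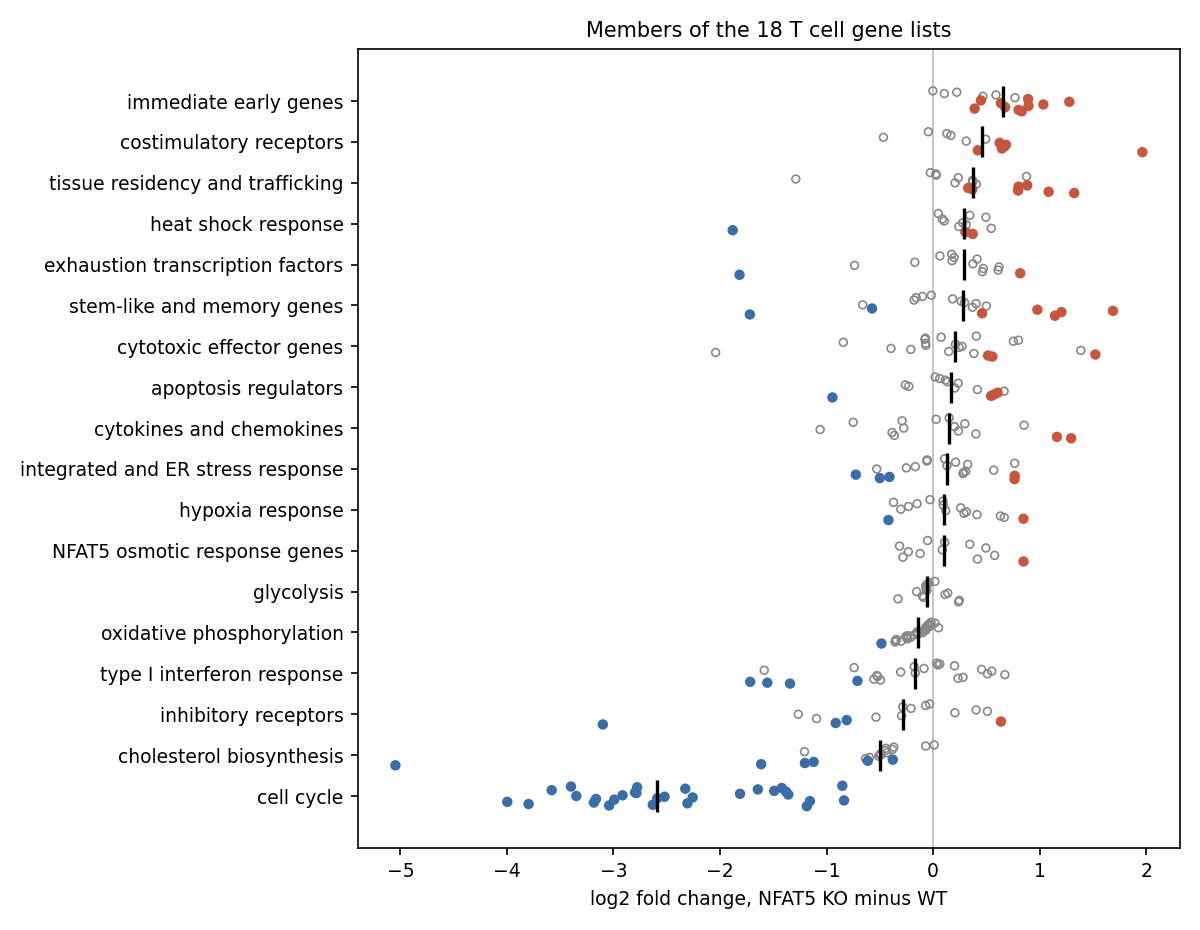
Log2 fold change of NFAT5 KO minus WT (x axis) for the tested members of each of the 18 T cell lists (y axis), with filled points for genes past the adjusted p threshold, open points for the others and a bar at the list median. Medians run from -2.59 for the cell cycle to 0.66 for immediate early genes.

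Several genes with the smallest p-values belonged to none of the lists. Napsa (chromosome 7, 44572380 to 44586862), an aspartic protease gene, fell from 37.95 ± 6.77 to 6.01 ± 0.765 CPM (log2 fold change -2.66, SE 0.17, adjusted p = 1.35e-05). Rbpj-ps3, annotated as a pseudogene, fell by 3.30 (SE 0.23), while its parent gene Rbpj had a log2 fold change of 0.37 (adjusted p = 0.134), and reads of such a pair can be assigned to the wrong copy. Higher in NFAT5 KO were Arap2 (1.03, SE 0.15), Fam160a2 (1.02), Acss2, which makes acetyl-CoA from acetate (1.01), Prkx (0.79) and Chil5 (3.52, from 0.366 to 4.21 CPM). The unnamed gene models Gm37758 and AC160336.1 rose by 1.44 and 0.66.

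The V segments of the transgenic receptor were higher in NFAT5 KO libraries. Trav14-1 (chromosome 14, 53554022 to 53554558) rose from 228 ± 32.4 to 434 ± 76.8 CPM, a log2 fold change of 0.93 (SE 0.13, adjusted p = 0.000968), and Trbv13-3 was the second of 6 tested segments to rise. The list had a median of 0.55 (adjusted p = 0.0293, and adjusted p = 0.154 with an estimated correlation). Adjusted over the list alone 3 segments rose. The 140 other alpha and beta V segments summed to 51.3 ± 3.84 CPM in WT and 45.8 ± 8.25 CPM in NFAT5 KO libraries.

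Markers of macrophages and monocytes were lower in NFAT5 KO libraries, with a median of -1.68 over 15 tested genes (adjusted p = 0.00105, and adjusted p = 0.154 with an estimated correlation). Spp1 fell from 114 to 3.15 CPM, and Adgre1 and Ctsb also fell, while Ccr2, which T cells express as well, rose. Spp1 did not follow Lyz2 in each library. Spp1 stood at 119 CPM in WT 678_4 and 6.86 CPM in NFAT5 KO 679_6. In the same libraries Lyz2 stood at 18.9 and 31.9 CPM and C1qb at 5.55 and 3.72 CPM. The fall of Spp1 alone therefore does not measure macrophage content. Adjusted over the list alone, 3 fell and 1 rose. The marker mean per library differed at an exact permutation p of 0.0159 (Benjamini-Hochberg adjusted p = 0.0742, two-sided). B cell markers had a median of -0.70 over 3 tested genes (adjusted p = 0.0352, and adjusted p = 0.154 with an estimated correlation), of which Ighm passed over all genes (from 419 ± 141 to 257 ± 24.0 CPM) and 3 passed adjusted over the list alone. Without NFAT5 KO 678_6 or 679_6 its adjusted p was 0.0610 or 0.0628. With a filter of at least 5 CPM in at least 5 libraries the macrophage and B cell lists had medians of -0.708 and -0.661 and lost their calls (adjusted p = 0.106 and 0.14). The lists of melanoma cells, dendritic cells, fibroblasts, endothelial cells, natural killer cells and CD4 or regulatory T cells were not called (adjusted p = 0.400, 0.494, 0.244, 0.400, 0.494 and 0.239). In the same order they had 3, 5, 2, 2, 4 and 5 tested genes. Some of these, such as Gzma and Cd40lg, also belong to the T cell lists, so the tests say little about the content of those cells. No marker of neutrophils or erythroid cells passed the low-count filter. Genes encoded by mitochondria and cytosolic ribosomal proteins were not called (medians 0.12 and -0.03, adjusted p = 0.494 and 0.788). The mitochondrial list ran from -0.043 to 0.269 with 1 library left out and was called higher without NFAT5 KO 678_5 (0.266, adjusted p = 0.0116). Of the sex-linked genes Xist alone passed the low-count filter, and it did not differ between genotypes at the threshold.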

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

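The tests of macrophage RNA, of T cells with other receptors and of swapped labels in part of the libraries were chosen only after the results they bear on had been seen.

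Of 258 groups of 5 libraries examined, 18 held a library far from the other 4 (Dixon's test), where chance gives about 1 in 20. In log2 CPM, Nfat5 stood at 4.75 in NFAT5 KO 679_2 (the others 3.54 to 3.66). The same library stood apart for Cd28 at 8.75, Pdk1 at 6.43 and Fas at 5.49, and for the mean of the stem-like and memory genes at 6.99 (the others 6.72 to 6.76). NFAT5 KO 678_3 stood apart for Dusp1 at 8.63 and Fdft1 at 4.92, NFAT5 KO 678_5 for Acss2 at 5.76 and Psat1 at 5.37, and NFAT5 KO 679_6 for Egr2 at 6.45 (the others 7.05 to 7.11). WT 678_4 stood apart for Mcm2 at 8.46 and Cd28 at 8.43. WT 679_4 did so for Rsad2 at 4.38 and Cyp51 at 6.77, and for the mean of the apoptosis regulators at 6.09. WT 679_5 was the shallowest WT library at 22444310 estimated counts (the others 29111790 to 30700567) and had the highest mean of the neutrophil markers at -1.62 (the others -3.31 to -2.99). In WT 678_2, 0.85% of the counts came from ribosomal RNA genes, mitochondrial ones included (the others 0.59% to 0.63%).

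A chance division of the libraries is an unlikely reason for the number of changed genes. Of 100 splits of the 10 libraries into 5 and 5, 1 gave as many genes as the real one, and that was the real split itself, with 1179 genes against at most 0 in the others. With 100 splits the smallest share that can be found is 1 in 100. The other splits mixed the genotypes, so the difference between genotypes widened the spread within their groups and may have lowered their counts.

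The first pattern is the lower expression of the cell cycle list in NFAT5 KO cells. Macrophages also divide, and their markers were lower in the same libraries, but the WT libraries exceeded the NFAT5 KO libraries by 3758 CPM in the sum of the 29 cell cycle genes and by 275 CPM in the sum of the 18 macrophage markers. The gap of 3483 CPM (SE 466) argues against macrophage RNA as the whole source, since the most abundant macrophage genes would have to rise at least as much. Ctsb made up most of the macrophage sum (654 CPM in WT and 512 CPM in NFAT5 KO) and Ccr2 rose, so that sum is a rough measure of macrophage RNA. One library did not decide the pattern, as the list median stayed between -2.84 and -2.42 with each library left out. With log2 library size in the model the genotype difference of the list mean was -2.49 (SE 0.30) against -2.50 without it, which argues against depth. With the macrophage mean in the model the difference was -1.85 (SE 0.36), so a link between macrophage content and the size of the difference stays open, as does a different size of the tumours at harvest, which was not tested. A lower share of dividing T cells in NFAT5 KO tumours is a candidate explanation in keeping with these tests, found and tested on the same libraries.

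The second pattern is the higher level of the P14 receptor segments in NFAT5 KO libraries. If WT libraries held more T cells with other receptors, other V segments would make up for the 292.4 CPM that Trav14-1 and Trbv13-3 lacked there, but the excess of the 140 other segments in WT was 5.5 CPM (SE 4.1). A dilution of T cell RNA in WT libraries would raise T cell identity genes alike in NFAT5 KO. Yet the median log2 fold change of 12 such genes was 0.164, with Cd8a at -0.03 and Cd3e at 0.13. The SE of the mean, 0.072, was taken over the 12 genes and does not measure the spread between libraries. A higher expression of the receptor transgenes in each T cell stays open as a hypothesis. The identity gene Cd2 (0.46) was also higher.

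The third pattern is that the count of Nfat5 did not differ between genotypes. With swapped labels in part of the libraries, the values would place at least 1 library of each genotype on the side of the other, and 0 of the 10 libraries lay there on the first principal component. That argues against a swap of some libraries between the groups. An exchange of all labels would give the same picture and stays open, and the test says nothing of how complete the deletion was. Reads outside the floxed part of the gene stay a candidate explanation, and the tables used here do not give counts per exon.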

How the results depend on the processing

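The median log2 fold change of the cell cycle list lay between -2.84 and -2.03 in every alternative run, with the list called in each. The next counts leave out Nfat5. Of 1112 values of the other named genes under the alternatives that keep or split the libraries, 853 kept their direction and side of the threshold, 252 kept the direction but no longer passed, 6 turned direction and 1 came to pass (Slamf6). With 1 library left out the numbers, also without Nfat5, were 803, 120, 6 and 1 (again Slamf6) of 930. Of the 83 named genes past the threshold, 57 passed without any one library.

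The number of changed genes was 0 in prefix 678 alone (0 higher, 0 lower), 325 in prefix 679 alone (71 higher, 254 lower), 654 with the melanoma covariate (205 higher, 449 lower) and 2 with the macrophage covariate (0 higher, 2 lower, Napsa and Rbpj-ps3). The prefix fits had 5 libraries each. With the macrophage covariate the 1179 genes all kept their direction. Their median absolute log2 fold change went from 0.824 to 0.660 and the median SE from 0.175 to 0.274, and 690 kept an unadjusted p below 0.05. The calls ended because the covariate follows genotype (r = -0.78), which widened the errors, and because the folds shrank. With the label prefix as a block 976 genes were called (341 higher, 635 lower), with 8 lists called as before. In that fit 6 named genes no longer passed, among them Bcl6 (adjusted p = 0.0648), Tnfsf14 (0.0594), Pfkfb3 (0.0532), Cox5b (0.0556) and Psat1 (0.0604). With the length offset 8 named genes no longer passed. Among them were Fdft1 (adjusted p = 0.109), Itgb7 (0.0797), Xaf1 (0.0676), Ddit3 (0.0574), Tnfrsf18 (0.0553), Tnfrsf9 (0.0527) and Bcl6 (0.0508). The DESeq2 Wald test called 1893 genes, 811 of them higher. Leaving out 1 library gave 696 (WT 678_2) to 1276 (WT 678_4) genes, 202 to 490 of them higher. With an estimated correlation 1 list was called instead of 8.

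The inhibitory receptor list lost its call at -0.256 with the stricter filter, -0.197 with the melanoma covariate, -0.107 with the macrophage covariate and -0.285 with an estimated correlation, and ranged from -0.370 to -0.242 with 1 library left out. The exhaustion transcription factors passed in prefix 679 alone (0.429). The stem-like list lost its call at 0.279 both with an estimated correlation and with fry, and ranged from 0.209 to 0.339 with 1 library left out. The cytotoxic list ranged from -0.011 to 0.264 and passed without NFAT5 KO 679_2. With the macrophage covariate, camera's direction turned for oxidative phosphorylation (-0.006) and for ribosomal proteins (0.162, now past the threshold). The P14 segments (0.457) and B cell markers (-0.699) lost their calls there. Heat shock genes were called with either other filter (0.276 and 0.293), in prefix 678 alone (0.288), with the DESeq2 Wald test (0.287) and with limma-voom (0.201). Interferon response genes were called with no filter (-0.187), in prefix 678 alone (-0.218) and with the macrophage covariate (-0.457). Glycolysis was called in prefix 679 alone (-0.214) and with limma-voom (-0.116), and the mitochondrial genes with limma-voom (0.295). Oxidative phosphorylation lost its call in prefix 679 alone (-0.107), with the melanoma covariate (-0.086) and with fry, and the B cell markers in prefix 679 alone (-0.903). With fry the apoptosis, fibroblast and endothelial lists passed.

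No result that turned direction had passed the threshold, except oxidative phosphorylation above. In prefix 678 alone these were the cytotoxic (-0.051), glycolysis (0.088) and CD4 or regulatory T cell (-0.088) lists, Ifng (-0.032) and Gzmb (-0.208), and in prefix 679 alone the hypoxia list (-0.191), ribosomal proteins (0.031) and Nfat5 (0.468). With limma-voom they were the osmotic (-0.093) and hypoxia (-0.157) lists, ribosomal proteins (0.026) and Gzmb (-0.141). With the macrophage covariate they were also the osmotic (-0.039), glycolysis (0.022) and melanoma (0.598) lists, Tcf7 (-0.008) and Il2 (0.34). Others were ribosomal proteins with the melanoma covariate (0.021), the osmotic list with the block (-0.022), Nfat5 with the length offset (0.068), Ifng with library size alone (-0.013), fibroblasts with no filter (-0.406) and natural killer cells with the stricter filter (0.403). With 1 library left out, ranges across 0 were -0.078 to 0.165 for the osmotic list, -0.172 to 0.016 for glycolysis, -0.086 to 0.204 for hypoxia, -0.043 to 0.269 for the mitochondrial genes, -0.091 to 0.041 for ribosomal proteins and -0.105 to 0.189 for CD4 or regulatory T cells. Such ranges of genes were -0.368 to 0.025 for Nfat5, -0.047 to 0.059 for Ifng, -0.227 to 0.212 for Gzmb and -0.033 to 0.32 for Slc2a1. The causes of all these changes were not tested.

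Scaling moved the median over all genes by little, from 0.017 to -0.026 with library size alone. Genes of a few CPM, such as Il2 and most markers of other cells, are those whose folds the depth limits.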

Other observations

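The genes named in the next 2 paragraphs were chosen after their values were seen, and the test of gene families was also added then.

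Further genes changed with genotype, and no shared function of them was tested. Klf3, a transcription factor of the family that guides T cell trafficking, rose from 16.2 to 56.8 CPM (log2 fold change 1.81, SE 0.32) and Ccr8, a chemokine receptor gene, from 11.9 to 36.0 CPM. Ifngr1, which encodes a chain of the interferon gamma receptor, rose by 0.94 (SE 0.17), Relb by 0.91 (SE 0.18) and Cd7 by 1.09 (SE 0.22). The cell cycle inhibitor gene Cdkn1a rose from 58.7 to 146 CPM (adjusted p = 0.0450). Among the lower genes, Klre1, which encodes a lectin-like receptor and belongs to the fixed natural killer cell list, fell from 47.5 ± 12.9 to 15.3 ± 1.53 CPM, and the gene model Gm156 from 101 to 1.71 CPM. Nrgn, which encodes a calmodulin-binding protein, fell from 85.4 to 4.94 CPM, Vim from 311 to 99.7 CPM, Lgals1 from 770 to 337 CPM and Xdh from 461 to 201 CPM.

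Epdr1 had no counts in any of the 5 NFAT5 KO libraries and 5.26 ± 2.41 CPM in WT. The WT mean was 235-fold above a floor of 3 counts over the 5 NFAT5 KO libraries. That ratio leaves out the spread between libraries, and the lowest WT library held 3.54 CPM. Of the 1179 changed genes, 3 others had no counts in the NFAT5 KO group, namely Tpbgl, Cd300c2 and Gm46519, with 1.90, 0.759 and 0.710 CPM in WT.

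Genes were also grouped into 193 families of at least 8 tested genes by the letters that begin their symbols, and tested with camera. The preset correlation called 10 families, and an estimated correlation called 0. The lower ones were Mcm (8 of 10 genes fell, median -1.27), Hist (13 of 43, median -1.58), Rad (7 of 18), Kif (9 of 28), Cdc (6 of 25) and Haus (3 of 8), whose members serve replication, chromatin, DNA repair or mitosis. Reads of histone genes are shared among near-identical copies, so single histone genes are uncertain. The higher ones were Nr (3 of 14, among them Nr4a1 and Nr3c1, the glucocorticoid receptor gene), Dnajb (3 of 10), Gimap (1 of 9) and Zbtb (3 of 37).

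One hypothesis was that part of the changed genes mark DNA of another mouse strain, which may show as a cluster of changed genes. Per the labels both genotypes carried floxed Nfat5 alleles, so DNA that they share around that locus would not differ between them. The hypothesis therefore concerns DNA kept around the Cre locus. Of 409 windows of 5 Mb, with histone and Klr genes left out, 0 held more changed genes than chance gives (smallest adjusted p = 0.841). The test would miss a short segment or one with few expressed genes, so the question stays open for the Cre locus.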
